A study of Homo sapiens with 12 samples.

How the data were processed

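Total RNA was taken from cultures of 2 established human retinoblastoma cell lines, WERI-Rb-1 (written WERI here) and Y79. The cultures had been exposed for 12 h to 50 nM THZ1 or to 0.1% DMSO, with 3 cultures per group and 12 in all. Per the labels, the libraries were made with a NEBNext Ultra RNA kit, which does not keep the strand of the transcript, and the authors' processing notes name Cufflinks and the genome build GRCh38. The version of Cufflinks, the aligner and the way reads were counted are not given in the sources used here.

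The deposited table holds whole-number counts per gene, and the authors applied no normalization to them that the values show. It has 27505 features, of which 19974 are Ensembl genes and 7531 are unannotated loci without coordinates. All Ensembl genes (100%) were found in GENCODE v29, and 19922 of them are protein coding there. Counts of 1 were rarer than counts of 2 in every library, with 172 features at 1 and 593 at 2 in the first WERI control library. Whether a read pair adds 1 or 2 to a count is not given in the sources used here, so very low counts are read with caution. In the table, 27 symbols had been turned into dates and were restored from the Ensembl identifier, and 15 symbols were shared by several identifiers. Positions are those of GENCODE v29 on GRCh38. Gene symbols are printed as in the table, which uses the older histone names.

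Total counts ranged from 29677575 to 37433574 per library. A count of 0 in a library of this size leaves room for up to 3 counts, and this floor of 3 counts per library was used for every fold against a group without counts. Such floors cover counting error only.

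The counts were analysed in R 4.3.3 with edgeR 4.0.16. Features with low counts were removed by filterByExpr with its default settings, which left 14865 Ensembl genes and 3979 unannotated loci. Libraries were scaled by TMM factors, which assume that most genes do not change. A quasi-likelihood model with robust spread estimates (glmQLFit, glmQLFTest) was fitted to all 12 libraries with 1 mean per group, leaving 8 residual degrees of freedom before moderation. Replicate numbers were not used. The 4 contrasts were THZ1 against DMSO in WERI, the same in Y79, the difference between these changes (Y79 minus WERI), and Y79 against WERI in DMSO. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested features of a contrast. A gene was called at an adjusted p under 0.05, and printed numbers of genes cover Ensembl genes. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM stands for counts-per-million with TMM scaling.

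Shares of counts were compared by an exact permutation test, two-sided, whose smallest p with 3 against 3 libraries is 0.1. Symbols and identifiers were matched, shares computed and figures drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

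Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 27 lists of a contrast. Beside it stand camera with an estimated correlation and fry, which does not compare a list with other genes. The lists cover THZ1 targets, core TFIIH subunits, polymerase II elongation, the MYC family, MYC targets, photoreceptor genes, retinal progenitor genes, inner retinal neuron genes, glial and pigment epithelium genes, stromal and blood genes, immediate early genes, anti-apoptotic genes, pro-apoptotic genes, p53 targets, G1/S and replication genes, G2/M and mitosis genes, homologous recombination repair genes, integrated stress response and ER stress genes, heat shock genes, ribosomal proteins, mitochondrially encoded mRNAs, nuclear respiratory chain genes, glycolysis genes, cholesterol synthesis genes, interferon and NF-kB genes, replication-dependent histones, and RB pathway genes and retinoblastoma oncogenes. The list named THZ1 targets holds the kinases CDK7, CDK12 and CDK13 and also their partners CCNH, MNAT1 and CCNK. Of 743 list entries, 740 were matched to a feature. Called members were counted with p adjusted over all tested features and, where the number differs, also adjusted over the list alone. The estimated correlation was 0.939 for ribosomal proteins and 0.771 for nuclear respiratory chain genes. It lay near the preset for other lists, at 0.015 for G1/S and replication genes, 0.006 for p53 targets and -0.002 for the MYC family. A call lost with an estimated correlation therefore need not mean that the members were correlated.

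The genes named in the text follow a rule. CDK7, CDK12, CDK13, MYCN and MYC were always named, except that the rule for the difference between the lines did not list them. For each THZ1 comparison and for the comparison of the lines in DMSO, the 6 largest rises and 6 largest falls were named among called genes with an average log2 CPM of at least 3 and no overlap of CPM between the groups. For the difference between the lines, the 5 largest positive and 5 largest negative values were named without the overlap condition. For each called list, the 2 called members with the largest change in the direction of the list were named. Features without a symbol, Y-linked genes and XIST were left out. Other genes appear as further members of lists, or as the exceptions where a list had few members against its direction, and those were chosen after their values were seen.

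The groups, contrasts, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 with its Wald test, RLE factors, library size only, scaling to the 13 mitochondrially encoded mRNAs, no filter on low counts, a CPM of at least 1 in 3 samples, a replicate block, the samples of a comparison alone, a log2 fold change of at least 1, and leaving out each of the 12 libraries in turn. Leaving unannotated loci out of the fit was added after the data were seen, as were the list counts under library size, under mitochondrial scaling and without replicate 2 or replicate 3 of the treated Y79 group. Mitochondrial scaling without treated Y79 replicate 2, medians with bounds under the other scalings and calls of unannotated loci under mitochondrial scaling were likewise added after the data were seen. When a library was left out, its group kept 2 libraries and the spread was estimated over all groups.

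The procedure was tested on simulated data with known changes in annotated genes. Recovery at a fold of 2 was 65.7% for THZ1 in WERI, 58.2% for THZ1 in Y79, 47.8% for the difference between the lines and 77.6% for the lines in DMSO. At a fold of 4 these shares were 86.4%, 83.3%, 68.2% and 89.4%, and from 3 to 15 unchanged features were called per contrast. A simulated list of 40 genes shifted by a fold of 1.5 was found in each contrast, and none of 26 random lists was called. Simulated genes varied independently and few of them were changed, unlike the genes of these data. The simulation therefore does not measure errors where list members are correlated or most genes change. A first form of this test drew changed genes from all features and missed its own limit on recovery, so it was rewritten for annotated genes with other limits.

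Of 84 named genes, 30 share exon bases with another gene of the basic annotation, 18 share them with a protein-coding gene, and 22 with a gene on the opposite strand. Counts of such genes can hold reads of the neighbour, since the libraries do not keep the strand. Levels of the protein products and the amount of RNA per cell were not analysed here. Values of some single members of the lists are not reported here.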

Results

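The transcriptomes of 2 retinoblastoma cell lines were measured by RNA sequencing after exposure to THZ1. THZ1 is a covalent inhibitor of the kinase CDK7 that also binds CDK12 and CDK13. WERI-Rb-1 (WERI) and Y79 are established human lines grown from tumours of the retina. Each line was kept for 12 h in 50 nM THZ1 or in 0.1% DMSO, the solvent, which gave 4 groups of 3 cultures. The 12 libraries held from 29677575 to 37433574 counts. WERI control libraries held 33913113, 32839170 and 36115270 counts, and treated WERI libraries 31189395, 31286687 and 31801650. Y79 control libraries held 37433574, 35192827 and 36903393 counts, and treated Y79 libraries 35095844, 29677575 and 30027843. In all that follows n = 3 cultures per group, errors of group means are SD, errors of log2 fold changes are SE, and adjusted p comes from the edgeR model.

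THZ1 changed how each library was divided among classes of RNA. The 13 mRNAs encoded by the mitochondrial genome, which RNA polymerase II does not make, took 3.87% ± 0.111 (SD) of counts in WERI controls and 10.6% ± 0.726 in treated WERI cells. In Y79 their share was 4.20% ± 0.262 in controls and 9.28% ± 0.729 after THZ1. Ribosomal protein mRNAs, which are short, abundant and long-lived, went from 2.99% ± 0.182 to 6.54% ± 0.244 in WERI. In Y79 they went from 4.63% ± 0.047 to 12.1% ± 2.33. The mRNA of the elongation factor EEF1A1 alone took 0.470% of counts in WERI controls and 1.02% in treated cells, and in Y79 it took 0.866% and 2.32%. Unannotated loci rose from 2.77% ± 0.048 to 4.49% ± 0.121 in WERI and from 2.83% ± 0.068 to 4.74% ± 0.592 in Y79. Each of these differences separated all treated from all control libraries of a line, with an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 libraries allow.

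**Figure D1:**
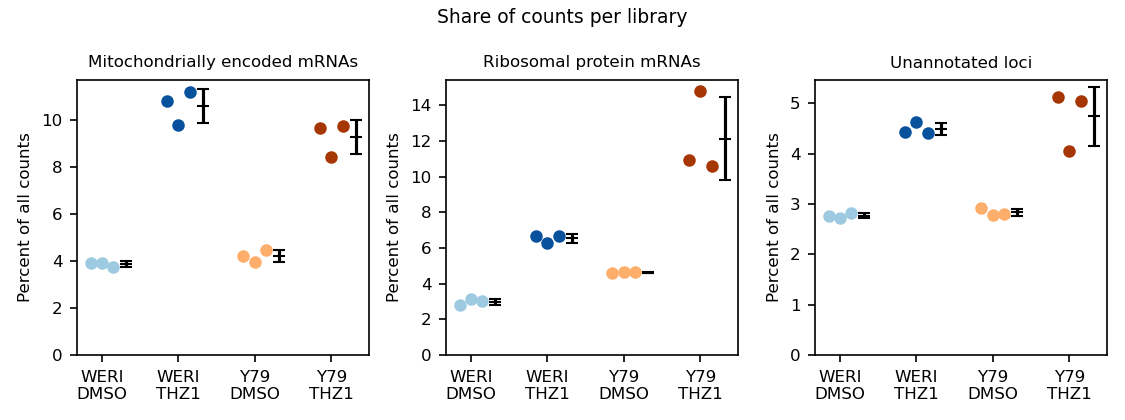
Percent of all counts taken by mitochondrially encoded mRNAs, ribosomal protein mRNAs and unannotated loci in each library (points, 3 per group), with the group mean and SD as black bars. The mitochondrial share lies near 4% in both control groups, with means of 3.87% and 4.20%, and at means of 10.6% and 9.28% after THZ1.

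The first comparison asked which transcripts changed in WERI cells when CDK7, the kinase that phosphorylates RNA polymerase II as it leaves promoters, was inhibited. CDK7 mRNA itself fell sharply. Most transcripts of the DNA replication and mitosis lists fell, although neither list was called with an estimated correlation (adjusted p = 0.126 and 0.269). Replication-dependent histone transcripts rose under TMM and with library size only, and under mitochondrial scaling 12 were higher and 7 lower, whereas the medians of the ribosomal protein, glycolysis, nuclear respiratory chain and immediate early lists were positive against the typical gene and negative against mitochondrially encoded mRNAs. MYCN, the oncogene amplified in a subset of retinoblastomas, fell by less than most of the lowered replication genes.

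Of 14865 genes tested in WERI, 4115 were higher and 5523 lower after THZ1, which is 64.8% of the genes. At least 2-fold changes were found for 1680 higher and 2476 lower genes. The balance of rises and falls depended on the scaling. With TMM the median log2 fold change was -0.11, and 42.7% of the called genes were higher. With library size alone 2221 genes were higher and 7961 lower (median -0.56), and relative to the mitochondrially encoded mRNAs 111 were higher and 13328 lower (median -2.01). Fold changes below are those under TMM and are relative to the typical gene.

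CDK7 (ENSG00000134058, chromosome 5, 69234795 to 69277430 on GRCh38) went from 11.1 ± 1.13 CPM in controls to 3.00 ± 0.240 CPM in treated WERI cells (SD). This was a 3.71-fold fall, with a log2 fold change of -1.89 ± 0.126 (SE, adjusted p = 1.9e-08). The other kinases bound by THZ1 did not pass the threshold, with log2 fold changes of 0.04 ± 0.116 for CDK12 (adjusted p = 0.803) and -0.12 ± 0.114 for CDK13 (adjusted p = 0.378). Both were called lower with library size only (CDK12 at -0.41, adjusted p = 0.0282, and CDK13 at -0.57, adjusted p = 0.00341) and under mitochondrial scaling (-1.85, adjusted p = 4.52e-10, and -2.02, adjusted p = 1.14e-10). MYCN (ENSG00000134323, chromosome 2, 15940564 to 15947007) fell from 332 ± 11.6 to 253 ± 10.6 CPM, a 1.31-fold fall (log2 -0.39 ± 0.066, adjusted p = 0.000133). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) was low, at 0.953 ± 0.133 CPM in controls (35, 39 and 50 counts) and 2.04 ± 0.538 CPM after THZ1. Its log2 fold change was 1.09 ± 0.229 (adjusted p = 0.000876), and it was -0.82 under mitochondrial scaling.

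The largest rises in WERI included genes of the AP-1 transcription factor, which cells switch on within minutes of stimulation. FOSB rose from 1.62 ± 0.541 to 50.8 ± 7.20 CPM, a log2 fold change of 4.97 ± 0.213. FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) rose from 3.92 ± 0.273 to 76.6 ± 11.1 CPM, a log2 fold change of 4.29 ± 0.188 (adjusted p = 6.68e-10). The histone H3 genes HIST2H3C and HIST2H3A, near-identical copies with almost equal counts, rose by 4.07 ± 0.094 and 3.97 ± 0.083. H2AFJ, a histone H2A variant, had no counts in the controls and 11, 10 and 17 in treated libraries, at least 6.28-fold higher at the floor of 3 counts per library. NEUROG1, which encodes a proneural transcription factor, went from 0 counts to 8, 7 and 6, at least 3.47-fold higher. The largest falls were those of ZNF672 at -4.08 ± 0.109, the transporter gene SLC16A6 at -3.70 ± 0.131 and the mitochondrial ubiquitin ligase gene MUL1 at -3.31 ± 0.215. They were followed by the stress response factor DDIT3 at -3.24 ± 0.192, ZNF627 at -3.20 ± 0.151 and the DNA repair nuclease gene ERCC4 at -3.15 ± 0.130. DDIT3 shares exon bases with MARS on the opposite strand, so its counts can include reads of that gene.

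Replication-dependent histones, whose mRNAs normally lack a poly(A) tail, were higher for 22 of 33 tested members in WERI and lower for none (camera adjusted p = 7.11e-07). Their median log2 fold change was 2.71, and 1.65 with the 9 members that had a group without counts set to their bounds. Under mitochondrial scaling the medians were 0.95 and, with bounds, 0.00. This was the only list of the comparison called with an estimated correlation (adjusted p = 0.00723 with an estimated correlation). HIST1H4A went from 0 counts to 30, 22 and 23, at least 12.4-fold higher, and HIST1H4C rose by 6.35 ± 0.298 from 0.140 ± 0.0747 CPM. With so few control counts, the values describe only the histone RNA that entered the libraries. Whether the total amount of histone mRNA rose was not tested. Immediate early genes were higher for 21 and lower for 5 of 31 members (median 1.12, camera adjusted p = 2.34e-05, and adjusted p = 0.126 with an estimated correlation), with a median of -0.78 under mitochondrial scaling. EGR2, an early growth response factor, went from 0 counts to 8, 5 and 14, at least 4.47-fold higher. The neuronal early gene ARC rose by 3.54 ± 0.082 and EGR1 by 3.00 ± 0.137. The 5 lower members were the phosphatase genes DUSP5 (-1.90), DUSP2 (-1.52) and DUSP4 (-1.05) with FOSL2 (-1.08) and NR4A1 (-0.58).

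Genes of G1/S and replication were lower for 28 and higher for 10 of 38 members in WERI (median -0.93, camera adjusted p = 0.00223, and adjusted p = 0.126 with an estimated correlation). CCNE1, the cyclin that starts S phase, fell by 2.38 ± 0.122, and UHRF1, which maintains DNA methylation at forks, by 1.99 ± 0.061. Members that rose included the nucleotide synthesis genes TYMS (1.35) and RRM1 (0.70). Genes of G2/M and mitosis were lower for 28 and higher for 4 of 36 members (median -0.84, camera adjusted p = 0.000116, and adjusted p = 0.269 with an estimated correlation). CCNB1, the mitotic cyclin, fell by 2.21 ± 0.095 and the centromere histone gene CENPA by 1.94 ± 0.129. The 4 higher members were PRC1 (1.02), KIF4A (1.01), NUSAP1 (0.29) and FOXM1 (0.28). Both lists also had negative medians under library size and mitochondrial scaling.

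Ribosomal protein mRNAs were higher for 77 of 78 members in WERI and lower for 1, RPS26 (-0.82 ± 0.175), with a median of 1.55 under TMM and -0.35 under mitochondrial scaling (camera adjusted p = 5.17e-22). The call was lost when the correlation between members was taken from the data (adjusted p = 0.428 with an estimated correlation). Under mitochondrial scaling 0 members were higher and 41 lower. RPL37A rose by 2.03 ± 0.199 and RPS19 by 1.96 ± 0.183, but only by 0.13 and 0.06 without a call under mitochondrial scaling. Mitochondrially encoded mRNAs were higher for 13 of 13 members (median 1.86, camera adjusted p = 1.4e-08, and adjusted p = 0.195 with an estimated correlation), led by MT-ND3 at 2.19 ± 0.120 and MT-ND4L at 2.03 ± 0.249. Nuclear respiratory chain genes were higher for 34 and lower for 7 of 46 members, or 34 and 8 adjusted over the list alone, with a median of 0.77 that became -1.13 under mitochondrial scaling. Their camera adjusted p was 2.04e-05, and the adjusted p = 0.56 with an estimated correlation. COX6C rose by 1.89 ± 0.194 and UQCRQ by 1.72 ± 0.231, both slightly negative under mitochondrial scaling at -0.01 and -0.18.

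Glycolysis genes were higher for 14 and lower for 7 of 24 members in WERI, with a median of 0.89 that became -1.01 under mitochondrial scaling (camera adjusted p = 0.0274, and adjusted p = 0.486 with an estimated correlation). PGK1 rose by 1.62 ± 0.080 and PDK1 by 1.45 ± 0.102, while the glucose transporter genes SLC2A3 (-2.16) and SLC2A1 (-1.37) and the lactate dehydrogenase gene LDHA (-1.40) fell. Under mitochondrial scaling PGK1 stood at -0.28 and PDK1 at -0.45. Photoreceptor genes were higher for 19 and lower for 7 of 38 members, with a median of 0.43 that became -0.02 with library size alone and -1.47 under mitochondrial scaling (camera adjusted p = 0.0179, and adjusted p = 0.428 with an estimated correlation). The rod genes GNGT1 and PDE6A rose by 1.45 ± 0.276 and 1.43 ± 0.233, from 1.11 and 1.23 CPM, and stood at -0.44 and -0.47 under mitochondrial scaling. Among the 7 lower members were THRB (-2.04) and OTX2 (-1.53).

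The other 18 lists were not called in WERI, with camera adjusted p from 0.0558 to 0.805. Pro-apoptotic genes were lower for 10 and higher for 2 of 19 members (adjusted p = 0.0558), the higher members including BAX (0.50) and the lower ones BMF (-1.90) and BOK (-1.59). This list passed the threshold without replicate 2 of the controls (0.0432) or replicate 2 (0.0456) or 3 (0.0467) of the treated cells, with RLE factors (0.0471) and with no filter (0.0342). Cholesterol synthesis genes were lower for 13 and higher for 4 of 23 members, or 14 and 5 adjusted over the list alone (adjusted p = 0.0623, and 0.0467 without treated replicate 3, 0.0207 with library size only and 0.0316 with no filter), with MVK at -2.89. MYC targets were lower for 24 and higher for 10 of 42 members, among them the ribosome assembly genes BYSL (-2.68) and NOP16 (-2.33), and this list passed under mitochondrial scaling (0.0267). Homologous recombination repair genes were lower for 20 and higher for 4 of 36 members (21 and 4 adjusted over the list alone). Heat shock genes were lower for 11 and higher for 3 of 17 members, with the constitutive chaperone gene HSPA8 at -2.81. The p53 targets were lower for 16 and higher for 9 of 30 members (17 and 9 adjusted over the list alone), and integrated stress response and ER stress genes lower for 12 and higher for 10 of 29 members. Lower and higher members numbered 8 and 6 of 17 in the polymerase II elongation list (9 and 6 adjusted over the list alone), with HEXIM1 at 2.04, and 7 and 2 of 13 in the RB pathway list. The retinal progenitor list had 7 higher and 5 lower of 19 members, with a median of 0.33 and a mean of -0.19.

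Called members of the remaining lists in WERI were as follows. Higher and lower members numbered 4 and 4 of 9 in the MYC family, with a median of -0.11 and a mean of 0.02, and MYCL at -1.30. They numbered 2 and 4 of 9 among anti-apoptotic genes, with MCL1 at 0.29, and 2 and 3 of 7 among core TFIIH subunits, with GTF2H1 at -1.47. Among the 6 members of the THZ1 target list, 0 were higher and 2 lower, CDK7 and its partner MNAT1 (-0.66). Inner retinal neuron genes had 4 higher and 4 lower of 22 members (4 and 3 adjusted over the list alone), with a median of 0.12 and a mean of -0.03. Interferon and NF-kB genes had 5 and 3 of 20 (5 and 1 adjusted over the list alone), with a median of 0.09 and a mean of -0.05. Glial and pigment epithelium genes had 3 and 1 of 14, and stromal and blood genes 4 and 0 of 10.

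The second comparison asked the same question in Y79, a line with higher MYCN mRNA. The response resembled that in WERI, with falls of CDK7 and of most replication and mitosis transcripts under TMM, library size and mitochondrial scaling. Histone transcripts rose in Y79 under each of these scalings. Under mitochondrial scaling 22 were higher and 2 lower in Y79, against 12 and 7 in WERI. The replication and mitosis lists were not called with an estimated correlation (adjusted p = 0.235 for both). MYCN fell further than in WERI, and both CDK12 and MYC fell. The chaperone gene HSPA8 lost most of its mRNA.

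In Y79, 4439 genes were higher and 5721 lower after THZ1, which is 68.3% of the genes tested. At least 2-fold changes were found for 2144 higher and 2953 lower genes. With TMM the median log2 fold change was -0.09, and 43.7% of the called genes were higher. With library size alone 2175 were higher and 8334 lower (median -0.65), and relative to the mitochondrially encoded mRNAs 283 were higher and 12188 lower (median -1.80). Treated replicate 2 differed from its replicates, with ribosomal protein mRNAs at 14.8% of counts, and the others lay closer together.

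CDK7 fell from 19.3 ± 0.146 to 5.42 ± 0.337 CPM in Y79, a log2 fold change of -1.83 ± 0.122 (adjusted p = 1.28e-08). MYCN fell from 1233 ± 29.2 to 711 ± 20.4 CPM, a 1.73-fold fall (log2 -0.79 ± 0.066, adjusted p = 1.15e-07). MYC fell from 10.4 ± 1.35 to 5.56 ± 0.652 CPM (log2 -0.90 ± 0.204, adjusted p = 0.00156). CDK12 (ENSG00000167258, chromosome 17, 39461511 to 39564907), which supports transcription through long DNA repair genes, fell from 142 ± 2.75 to 58.2 ± 12.7 CPM (log2 -1.29 ± 0.119, adjusted p = 3.4e-07). CDK13 did not pass the threshold, at -0.21 ± 0.114 (adjusted p = 0.126), but did so without treated replicate 1 (log2 -0.34, adjusted p = 0.0188), with library size only (-0.76, adjusted p = 0.000341) and under mitochondrial scaling (-1.92, adjusted p = 2.35e-10).

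Apart from genes without counts in some control libraries, the largest rise among the better expressed genes was that of ID2 (ENSG00000115738, chromosome 2, 8678845 to 8684453), an inhibitor of differentiation factors. ID2 rose in Y79 from 7.19 ± 0.667 to 128 ± 12.8 CPM, a log2 fold change of 4.15 ± 0.096 (adjusted p = 4.06e-12). FOS rose by 4.13 ± 0.200, HIST2H3C by 4.11 ± 0.098 and HIST1H2BG by 4.09 ± 0.181. TSTD1, a sulfurtransferase gene that overlaps a neighbouring gene model, had 0, 0 and 2 counts in controls and 22, 43 and 20 in treated libraries (adjusted p = 1.89e-06). LYNX1, a modulator of nicotinic receptors, went from 0 counts to 2, 4 and 7, at least 2.54-fold higher, and is abundant in WERI. HSPA8 (ENSG00000109971, chromosome 11, 123057489 to 123063230) fell from 1825 ± 41.9 to 134 ± 18.6 CPM, a log2 fold change of -3.77 ± 0.099 (adjusted p = 8.19e-12). The other large falls were those of TTC4, a chaperone cofactor gene, at -3.99 ± 0.254, the splicing factor gene PRPF4 at -3.96 ± 0.103, the proton channel gene OTOP3 at -3.95 ± 0.219 and ZNF672 at -3.80 ± 0.110. SERPINB1, a protease inhibitor gene, went from 11, 8 and 10 counts to 0, at least 1.86-fold lower at the floor of 3 counts per library. With so few counts this bound would not hold if a read pair adds 2.

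Histones were higher for 32 of 33 tested members in Y79 and lower for none (median 3.27, camera adjusted p = 9.67e-13), and this was the only list called with an estimated correlation (adjusted p = 0.000695 with an estimated correlation). HIST1H4C rose by 5.31 ± 0.269 and HIST1H4A by 4.70 ± 0.697. Genes of G2/M and mitosis were lower for 31 and higher for 2 of 36 members, the latter PRC1 (1.00) and KIF4A (0.79) (median -0.81, camera adjusted p = 3.7e-06, and adjusted p = 0.235 with an estimated correlation). CCNB1 fell by 2.76 ± 0.098 and the mitotic kinase gene AURKA by 2.37 ± 0.096. Genes of G1/S and replication were lower for 26 and higher for 9 of 38 members (median -0.89, camera adjusted p = 0.00855, and adjusted p = 0.235 with an estimated correlation). GINS3, a subunit of the replicative helicase, fell by 2.66 ± 0.112 and the licensing factor gene CDC6 by 2.31 ± 0.073, while CCND2 rose by 1.37. Immediate early genes were higher for 18 and lower for 5 of 31 members, or 19 and 5 adjusted over the list alone, with a median of 1.15 that became -0.56 under mitochondrial scaling. Their camera adjusted p was 0.000882, and the adjusted p = 0.235 with an estimated correlation. FOSL1 rose by 5.09 ± 0.550 from control counts of 0, 2 and 6, and EGR2 went from 2, 0 and 0 counts to 9, 16 and 10. The 5 lower members were DUSP5 (-2.30), FOSL2 (-0.88), DUSP4 (-0.73), NR4A1 (-0.64) and DUSP1 (-0.50).

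Ribosomal protein mRNAs were higher for 78 of 78 members in Y79 (median 1.92, camera adjusted p = 4.58e-24, and adjusted p = 0.427 with an estimated correlation). Under mitochondrial scaling their median was 0.21 with 20 members higher and 1 lower, but -0.05 with 4 higher and 17 lower when treated replicate 2 was left out. RPS19 rose by 2.36 ± 0.185 and RPS9 by 2.22 ± 0.183. Mitochondrially encoded mRNAs were higher for 13 of 13 members (median 1.65, camera adjusted p = 2.18e-07, and adjusted p = 0.237 with an estimated correlation), with MT-CO1 at 1.91 ± 0.093 and MT-CO3 at 1.87 ± 0.115. Nuclear respiratory chain genes were higher for 32 and lower for 9 of 46 members, with a median of 0.82 that became -0.89 under mitochondrial scaling (camera adjusted p = 0.000695, and adjusted p = 0.629 with an estimated correlation). COX6C and UQCRQ rose by 1.95 ± 0.194 and 1.80 ± 0.231, but only by 0.23 and 0.10 without a call under mitochondrial scaling. Glycolysis genes were higher for 16 and lower for 6 of 24 members, with a median of 0.93 that became -0.78 under mitochondrial scaling (camera adjusted p = 0.00855, and adjusted p = 0.533 with an estimated correlation). GAPDH rose by 1.89 ± 0.107 and PDK1 by 1.63 ± 0.102, at 0.18 without a call and -0.08 under mitochondrial scaling, while SLC2A3 (-3.10), SLC2A1 (-2.56) and LDHA (-1.89) fell.

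The other 19 lists were not called in Y79, with camera adjusted p from 0.0667 to 0.963. Cholesterol synthesis genes were lower for 14 and higher for 6 of 23 members (adjusted p = 0.0667, and 0.0287 without treated replicate 2, 0.0306 with library size only and 0.029 with no filter), with HSD17B7 at -3.26 and MVK at -3.15. MYC targets were lower for 25 and higher for 12 of 42 members (adjusted p = 0.102, but 0.034 with library size only, 0.0445 with no filter and 0.0222 under mitochondrial scaling), with NOP16 at -3.69, CDK4 at -2.50 and NME2 at 2.01. Repair genes were lower for 21 and higher for 4 of 36 members (adjusted p = 0.102, but 0.0307, 0.0441 and 0.0106 in the same settings). Stromal and blood genes were higher for 5 and lower for 0 of 10 members (adjusted p = 0.16). This list passed with library size only (0.0252), with the stricter filter (0.0412) and under mitochondrial scaling (0.00164). Under mitochondrial scaling glial (0.00838) and interferon genes (0.00164) also passed, like the stromal list toward higher than other genes. Stress response genes (0.014) passed toward lower. Of the 6 members of the THZ1 target list, 4 were lower. These were the kinases CDK7 and CDK12 and the partners MNAT1 (-1.05) and CCNH (-0.87), and this list passed with no filter (0.0445). Photoreceptor genes were split, with 16 higher and 14 lower of 38 members, and again OTX2 (-1.94) and THRB (-2.36) fell. The retinal progenitor list had 9 higher and 10 lower of 19 members, with a median of -0.91, or 0.00 with the 1 member that had a group without counts at its bound, and its members included SOX4 (1.22) and RAX (-2.08). Medians and the direction of the test differed in sign for the retinal progenitor, inner retinal neuron, polymerase II elongation, p53, MYC family and anti-apoptotic lists, whose camera adjusted p ranged from 0.509 to 0.963.

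**Figure D2:**
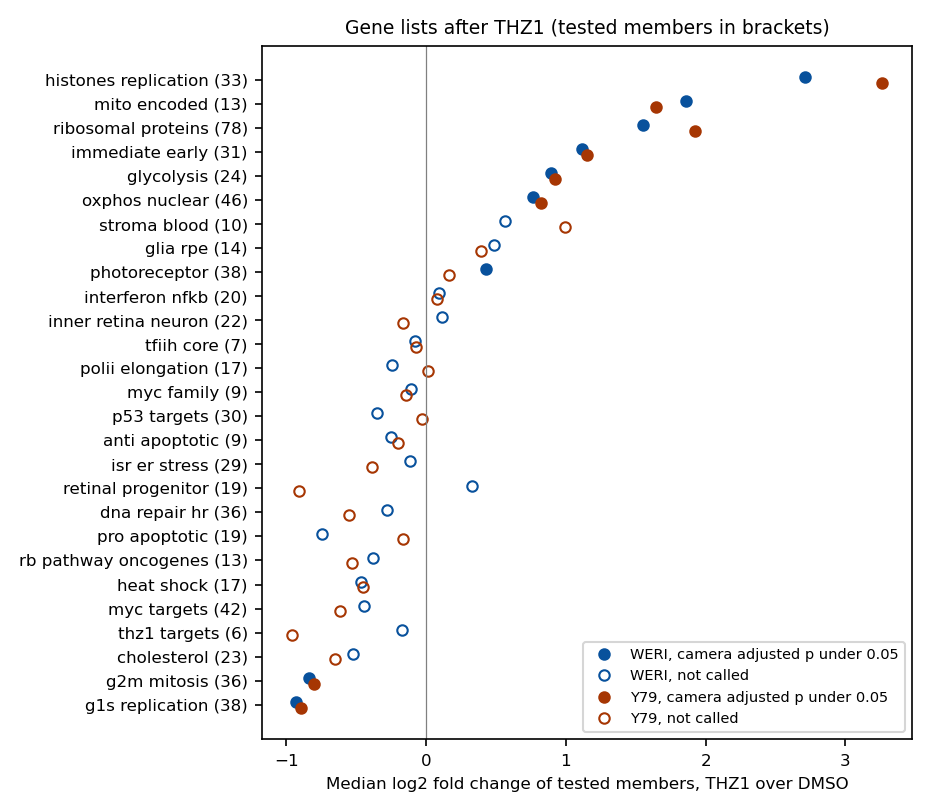
Median log2 fold change after THZ1 of the tested members of each gene list in WERI (blue) and Y79 (brown) under TMM scaling; filled points have a camera adjusted p under 0.05. Histones stand at 2.71 and 3.27, or 1.65 in WERI with members without counts at their bounds, which becomes 0.00 when scaled to mitochondrially encoded mRNAs. In contrast, the rises of nuclear respiratory chain, glycolysis and immediate early genes in both lines, and of ribosomal protein and photoreceptor genes in WERI, turn negative under that scaling.

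The third comparison asked whether the lines responded differently, by testing the change in Y79 minus the change in WERI. The responses largely ran in parallel, and Y79 had the wider range. Under TMM MYC rose in WERI and fell in Y79, CDK12 was called lower in Y79 alone, and MYCN fell more in Y79. For CDK7 and CDK13 no difference was called.

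Across 10121 genes with an average log2 CPM of at least 3, the log2 fold changes of the lines had a Pearson correlation of 0.85 and a Spearman correlation of 0.883. These are correlations across genes, which are not independent replicates. The SD of the log2 fold changes was 0.929 in WERI and 1.08 in Y79. In both lines 3245 genes were called higher, where 1229 would be shared if the calls were independent, and 4593 lower (2126 if independent). Opposite calls were made for 144 genes higher in WERI and lower in Y79, and for 115 genes lower in WERI and higher in Y79. The test of the difference called 1299 genes with a more positive and 1965 with a more negative change in Y79, or 22.0% of those tested, of which 284 and 358 differed at least 2-fold. With library size alone these numbers were 740 and 2696, and under mitochondrial scaling 1778 and 713, so the side with more calls depended on the scaling. They were 2161 and 3029 without replicate 2 of the treated Y79 group.

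**Figure D3:**
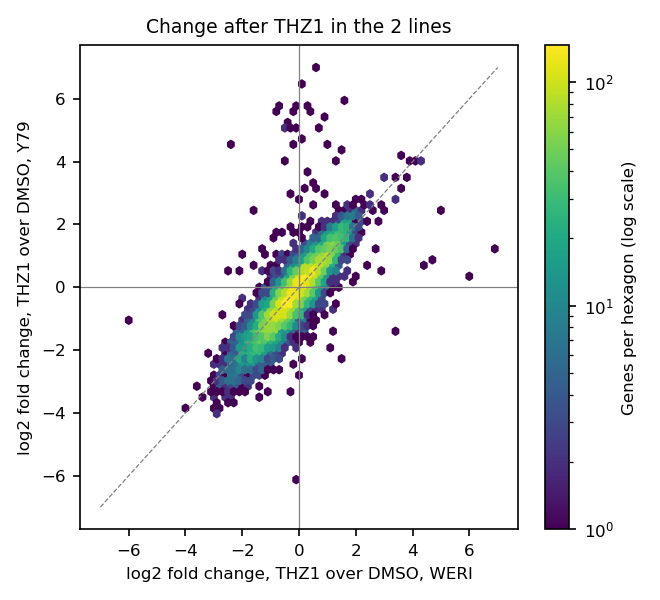
Log2 fold change after THZ1 in WERI (horizontal) and Y79 (vertical) for 10121 genes under TMM scaling, with the number of genes per hexagon in colour on a log scale and equality as a dashed line. Most genes lie along the diagonal (Spearman 0.883), and the few points far above it include genes with almost no counts in Y79 controls.

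The change of MYC differed by -1.99 ± 0.307 on the log2 scale (adjusted p = 0.000658) and that of CDK12 by -1.33 ± 0.166 (adjusted p = 0.000169). For MYCN the difference was -0.40 ± 0.093 (adjusted p = 0.00877), for CDK7 0.06 ± 0.171 (adjusted p = 0.879) and for CDK13 -0.09 ± 0.161 (adjusted p = 0.783). CEBPB (ENSG00000172216, chromosome 20, 50190734 to 50192689), a factor of stress and inflammatory responses, rose by 1.17 ± 0.277 in WERI and changed by -1.44 ± 0.328 in Y79, a difference of -2.61 ± 0.429 (adjusted p = 0.00111). FOSB rose less in Y79, by 2.46, a difference of -2.51 ± 0.279 (adjusted p = 7.19e-05). HSPA8 fell further in Y79, with a difference of -0.96 ± 0.126 (adjusted p = 0.000242), as did GINS3 at -1.23 and PRPF4 at -1.12. Among calls higher in both lines, 365 genes rose more in Y79 and 182 more in WERI. Among calls lower in both, 961 fell more in Y79 and 249 more in WERI. These numbers are those under TMM. Under mitochondrial scaling 1778 changes were called more positive and 713 more negative in Y79, so which line fell more depends on the scaling.

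**Figure D4:**
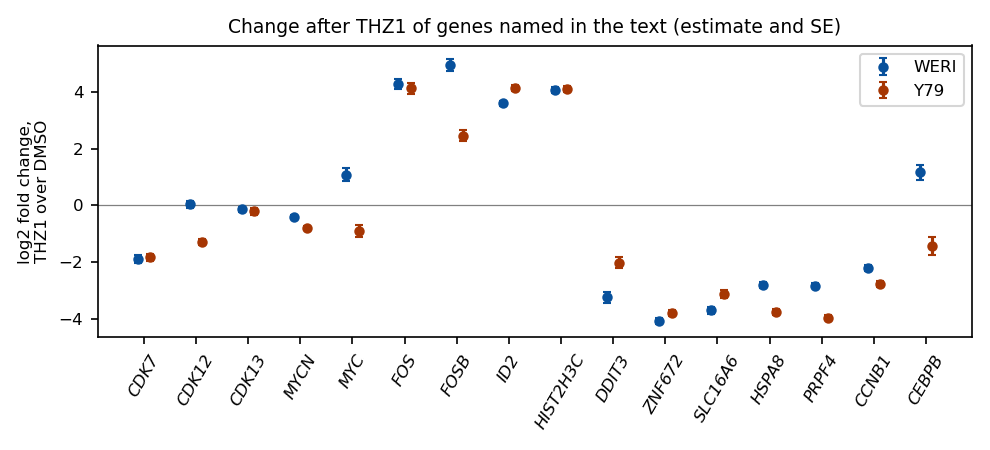
Log2 fold change after THZ1 with its SE for 16 genes of the text in WERI (blue) and Y79 (brown) under TMM scaling. CDK7 falls alike in both lines, at -1.89 and -1.83, while MYC (1.09 in WERI, but -0.82 there under mitochondrial scaling), CDK12 and CEBPB differ between them.

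The largest differences by size rested on genes that 1 of the lines barely used. H2AFJ and NEUROG1 had no counts in WERI controls, as given above, and differed by -5.75 ± 0.983 and -5.73 ± 0.914. SERPINB1 had few counts in Y79 and differed by -5.95 ± 0.718. RNF26, a ubiquitin ligase gene, had 0, 0 and 2 counts in WERI controls and 0, 5 and 12 in treated WERI libraries, and differed by -4.88 (adjusted p = 0.00543). Without replicate 3 of the treated WERI group its adjusted p was 0.0521. LYNX1 differed by 5.35 (adjusted p = 0.0015), and the desmosome gene DSC2 by 5.38 (adjusted p = 0.0158) with treated Y79 counts of 0, 6 and 3. CHRNB4, a nicotinic receptor subunit gene, had treated Y79 counts of 0, 0 and 6, and ZNF518B of 0, 6 and 6, and they differed by 6.98 and 6.43. H2AFY2, a macroH2A gene, had 0, 0 and 14, and differed by 6.42 (adjusted p = 0.0486). Without replicate 3 of the treated Y79 group the adjusted p was 1 for both CHRNB4 and H2AFY2, and H2AFY2 lost its call in 10 of the 12 settings that left out a library, all but those without replicate 1 or 2 of the treated Y79 group. Fitted folds of these genes depend on the model and are not bounds.

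Among the lists that differed between the lines the histones had the largest median, with 5 members rising more in Y79 and 1, HIST1H4J, rising less (median 0.45, camera adjusted p = 1.41e-05). They were the only list called with an estimated correlation (adjusted p = 0.0136 with an estimated correlation), while ribosomal proteins had the smallest camera adjusted p. In WERI 9 of the 33 members had a group without counts, so the histone difference includes members at the floor. Under mitochondrial scaling the histone call was lost (adjusted p = 0.0798), as was that of the G2/M and mitosis list (0.0731). Ribosomal protein mRNAs had a median difference of 0.38 (camera adjusted p = 6.72e-06, and adjusted p = 0.867 with an estimated correlation), with 8 members called, or 1 adjusted over the list alone. RPS26 (1.85) and RPL17 (0.73) were among them. Without replicate 2 of the treated Y79 group the ribosomal median was 0.13, with 25 members more positive and 4 more negative. Genes of G2/M and mitosis had a median of -0.27, with 14 more negative and 2 more positive in Y79, the latter CENPE (0.50) and NDC80 (0.34), or 17 and 4 adjusted over the list alone (camera adjusted p = 0.00461, and adjusted p = 0.609 with an estimated correlation). The kinase genes BUB1 (-0.94) and PLK1 (-0.57) and the cyclin gene CCNA2 (-0.84) fell more in Y79.

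The p53 targets had a median difference of 0.27, with 8 members more positive in Y79 and 3 more negative, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.0166, and adjusted p = 0.173 with an estimated correlation). GADD45A (1.40), MDM2 (0.91), BAX (0.77) and CDKN1A (0.44) were more positive, and SESN2 (-1.21), GDF15 (-0.62) and TIGAR (-0.39) more negative. Without replicate 1 of the treated WERI group the adjusted p of this list was 0.0525. Integrated stress response and ER stress genes had a median of -0.21, with 11 members more negative and 1, DDIT3 (1.22), more positive, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.038, and adjusted p = 0.67 with an estimated correlation). CHAC1 (-1.89), XBP1 (-1.14), HSPA5 (-0.95) and PPP1R15A (-0.93) were among the former. The call of this list was lost without replicate 3 of the WERI controls (adjusted p = 0.0541), replicate 1 of treated WERI (0.0595), replicate 3 of the Y79 controls (0.0515), or replicate 1 (0.138) or 3 (0.107) of treated Y79. It was also lost with the replicate block (0.0656) and the stricter filter (0.0571). The other 22 lists were not called, with camera adjusted p from 0.155 to 0.967. Without replicate 2 of treated Y79, MYC targets, photoreceptor genes (both 0.018) and nuclear respiratory chain genes (0.000965) passed the threshold, and without replicate 2 of treated WERI the mitochondrially encoded mRNAs did (0.0215).

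The fourth comparison set the lines against each other in DMSO, to show where each started. Y79 cells had more MYCN and MYC mRNA, and most MYC target, ribosomal protein and nuclear respiratory chain genes were higher there. These lists were not called with an estimated correlation (adjusted p = 0.311, 0.638 and 0.638). Most genes of the mitosis and interferon lists were higher in WERI, with IFI44L, IFI44 and ISG15 among the exceptions, and these lists too were not called in that way (adjusted p = 0.549 and 0.129). RB1, the retinoblastoma gene, was almost without counts in WERI.

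In DMSO 4802 genes were higher and 4844 lower in Y79 than in WERI, which is 64.9% of the genes tested. At least 2-fold differences were found for 1572 higher and 2721 lower genes. With library size alone 3641 genes were higher and 5732 lower, and under mitochondrial scaling 2706 were higher and 6322 lower, with medians of -0.16 and -0.27 against 0.00 under TMM. MYCN stood at 332 ± 11.6 CPM in WERI and 1233 ± 29.2 CPM in Y79, a log2 difference of 1.89 ± 0.068 (adjusted p = 3.09e-11). MYC was higher by 3.44 ± 0.228 (adjusted p = 1.49e-08) and CDK7 by 0.80 ± 0.115 (adjusted p = 3.99e-05). CDK13 was higher by 0.41 ± 0.114 (adjusted p = 0.00631, but 0.15 with library size alone and 0.405 under mitochondrial scaling). CDK12 did not pass the threshold at -0.10 ± 0.116 (adjusted p = 0.477), but did so in the DMSO samples alone (adjusted p = 0.00852) and under mitochondrial scaling (adjusted p = 0.0249). RB1 (ENSG00000139687, chromosome 13, 48303726 to 48599436), picked after its values were seen, had 0.0290 ± 0.0502 CPM in WERI and 49.7 ± 1.02 CPM in Y79 (log2 10.50 ± 0.359, adjusted p = 3.12e-11).

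Several genes were used by only 1 line. Without counts in WERI controls were the matrix gene MXRA5, at least 768-fold higher in Y79, DBNDD1 (at least 710-fold), H2AFJ (at least 486-fold), GAS8, a cilia gene that overlaps DBNDD1 on the opposite strand (at least 358-fold), and the Polycomb-related gene SFMBT2 (at least 299-fold). CA12, a carbonic anhydrase gene, had 583 ± 8.82 CPM in Y79 and 0, 0 and 6 counts in WERI. Without counts in Y79 controls were LRCH2, at least 1030-fold lower, TMEM179 (at least 902-fold), the desmosome gene DSG2 (at least 802-fold), the synaptotagmin gene SYT4 (at least 758-fold) and ZNF518B (at least 716-fold). VXN, a neurogenesis gene, had 307 ± 6.54 CPM in WERI and 0, 0 and 2 counts in Y79.

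MYC targets, mostly genes of ribosome assembly, were higher in Y79 for 37 and lower for 1 of 42 members, the latter TERT (-1.56) (median 0.79, camera adjusted p = 7.82e-08, and adjusted p = 0.311 with an estimated correlation). RRP9 was higher by 1.72 ± 0.162 and FBL by 1.46 ± 0.164. The MYC family had 7 higher and 1 lower of 9 members, the latter MYCL (-1.08) (median 0.60, camera adjusted p = 0.0131, and adjusted p = 0.129 with an estimated correlation). Ribosomal protein mRNAs were higher for 68 and lower for 1 of 78 members, RPL21 (-0.44), or 69 and 3 adjusted over the list alone (median 0.83, camera adjusted p = 1.1e-08, and adjusted p = 0.638 with an estimated correlation). RPL35A was higher by 1.86 ± 0.155 and RPL39 by 1.75 ± 0.152. Nuclear respiratory chain genes were higher for 33 and lower for 1 of 46 members, NDUFC1 (-0.56) (median 0.51, camera adjusted p = 2.57e-05, and adjusted p = 0.638 with an estimated correlation). ATP5F1A, the alpha subunit of ATP synthase, had 579 ± 12.9 CPM in WERI and 13720 ± 76.9 CPM in Y79 (log2 4.57 ± 0.133), and NDUFA1 was higher by 2.02 ± 0.157. Core TFIIH subunits, which form the complex of CDK7, were higher for 7 of 7 members (median 0.44, camera adjusted p = 0.0204, and adjusted p = 0.129 with an estimated correlation), with GTF2H3 at 0.82 ± 0.088 and GTF2H2 at 0.80 ± 0.108.

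Genes of G1/S and replication were higher in Y79 for 30 and lower for 1 of 38 members, CDC6 (-1.02) (median 0.37, camera adjusted p = 3.21e-05, and adjusted p = 0.0728 with an estimated correlation), with CCND2 at 3.34 ± 0.097 and GINS2 at 2.01 ± 0.111. Genes of G2/M and mitosis were lower for 22 and higher for 4 of 36 members (median -0.27, camera adjusted p = 0.0198, and adjusted p = 0.549 with an estimated correlation). KIF4A stood at -2.95 ± 0.078 and TOP2A at -1.64 ± 0.077, while CCNB2 (1.25), CKAP2 (0.94), CENPF (0.39) and HMMR (0.32) were higher. Glycolysis genes were higher for 16 and lower for 5 of 24 members, or 17 and 5 adjusted over the list alone (median 0.68, camera adjusted p = 0.0131, and adjusted p = 0.601 with an estimated correlation). PFKFB3 was higher by 7.27 ± 0.276 and ALDOC by 2.88 ± 0.240, and the lower members were SLC2A3 (-0.99), PFKFB4 (-0.95), HK2 (-0.76), PKM (-0.60) and SLC2A1 (-0.45). Interferon and NF-kB genes were lower for 13 and higher for 4 of 20 members, the latter IFI44L (4.49), IFI44 (3.13), ISG15 (2.03) and NFKBIA (0.45) (median -1.30, camera adjusted p = 0.0325, and adjusted p = 0.129 with an estimated correlation). MX1 and OAS3 had no counts in Y79 and were at least 14-fold and 4.98-fold lower. The call of OAS3 was lost with the replicate block (adjusted p = 0.0713). Histones were higher for 20 and lower for 6 of 33 members (median 1.27, or 0.83 with the 7 members without counts in a group at their bounds, camera adjusted p = 0.0365, and adjusted p = 0.129 with an estimated correlation). That call was lost with the stricter filter (0.104) and in the DMSO samples alone (0.17). HIST1H2BG and HIST1H3H had no counts in WERI and were at least 55.8-fold and 34.5-fold higher. All 10 lists called in DMSO kept the sign of their median under library size and mitochondrial scaling, but the interferon call was lost under both (adjusted p = 0.0716 and 0.0974) and the TFIIH call under the latter (0.0974).

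The other 17 lists were not called in DMSO, with camera adjusted p from 0.0985 to 0.982. The photoreceptor list was split, with 13 members higher and 20 lower in Y79 of 38 (13 and 22 adjusted over the list alone). The rod factors NR2E3 (5.44) and NRL (3.65) were higher in Y79, while THRB (-3.25), OPN1LW (-4.10) and PRDM1 (-4.67), of which the first 2 mark cones, were higher in WERI. Retinal progenitor genes had 6 higher and 10 lower of 19 members, with the cyclin gene CCND1 at 5.4 and the filament gene NES at -5.41, a median of -0.82 and a mean of 0.10.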

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

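Of the tests in this part, those of a rise of mitochondrial mRNA alone, of WERI material in a treated Y79 library and of a response of WERI genes in Y79 were chosen after the result was seen, as were the margin on the gene length test, the values without treated Y79 replicate 2, the other scaling of the unannotated loci and the breakdown of the drawn splits. The others were planned.

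The responses of the lines to THZ1 differed by a direct test (the change in Y79 minus the change in WERI, log2) for 28 of 57 genes named in the THZ1 comparisons or in their difference, 11 with a positive and 17 with a negative value. Genes named for the difference had to be called in this same test, and most others were picked for large changes. The 28 are therefore not an estimate of how often genes differ. Over all tested genes 22% were called. Among the genes named in advance the differences were -0.40 for MYCN, -1.99 for MYC and -1.33 for CDK12. Other negative values, which mean a lower change in Y79, were -2.61 for CEBPB, -2.51 for FOSB, -1.23 for GINS3, -1.12 for PRPF4, -1.09 for TTC4, -0.96 for HSPA8, -0.95 for OTOP3, -0.63 for CDC6, -0.56 for CCNB1 and -0.51 for AURKA. Genes with few or no counts in 1 line gave -5.95 for SERPINB1, -5.75 for H2AFJ, -5.73 for NEUROG1 and -4.88 for RNF26. Positive values were 1.22 for DDIT3, 0.58 for SLC16A6, 0.55 for ID2, 0.51 for GAPDH and 2.94 for FOSL1. Genes with few or no counts in Y79 controls gave 6.98 for CHRNB4, 6.43 for ZNF518B, 6.42 for H2AFY2, 5.38 for DSC2, 5.35 for LYNX1, 4.25 for TSTD1 and 2.94 for FOSL1. Median differences of lists were 0.38 for ribosomal proteins, 0.45 for histones, -0.27 for G2/M and mitosis, 0.27 for p53 targets and -0.21 for stress response genes. A difference in the biology of the lines remains an untested explanation for these, apart from the genes with few or no counts in 1 line. Those with positive values are weighed below, except FOSL1, which had 0, 2 and 6 counts in Y79 controls and was not weighed. Those with negative values were not weighed either.

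Among 3979 unannotated loci, which were part of the model but not of the numbers of genes in the report, 1352 were higher after THZ1 in WERI and 1458 in Y79, against 356 and 363 lower, all under TMM. Scaled to the mitochondrially encoded mRNAs, 329 were higher and 2176 lower in WERI, and 414 higher and 1780 lower in Y79. The locus with the most counts over all groups took 0.178% of counts in WERI controls and 0.663% after THZ1, and 0.196% and 0.511% in Y79. The next took 0.0557% and 0.484% in WERI and 0.0777% and 0.778% in Y79, more than the former in treated Y79 cells. These loci have no coordinates in the sources used here, so what they are was not tested.

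The numbers of called genes were set against other splits of the same libraries. The real split gave 9638 called genes for THZ1 in WERI, 10160 for THZ1 in Y79 and 9646 for the lines in DMSO, and the highest other split gave 0, 2 and 0. Each of these counts had 1 of 10 splits at least as large, the real one, and 10 splits are too few for a share under 0.05. For the difference between the lines, 7 of 100 drawn splits gave at least the real 3264 genes, and the highest gave 10961, so chance is not excluded by this number. The 6 others all kept the real split of treated and control in 1 line, as 17 of the drawn splits did. The highest of them exchanges treated and control in 1 line and so puts the shared response to THZ1 into the contrast, which is a structure of the samples. Among 82 splits that kept the real split in neither line, the highest gave 1 gene. Such splits mix treated and control libraries within a group, which widens the spread, so few calls follow from the mixing. The same holds for the other splits for THZ1 in WERI, THZ1 in Y79 and, with mixed lines, the lines in DMSO. The breakdown therefore does not decide whether chance explains the number for the difference.

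The first pattern weighed was the balance of rises and falls after THZ1, which TMM makes nearly even. Relative to the mitochondrially encoded mRNAs the median nuclear gene changed by -2.01 in WERI and -1.80 in Y79, and every treated library lay below every control library of its line. Ribosomal protein mRNAs changed far less against the mitochondrial ones, with a median of -0.35 in WERI and 0.21 in Y79, or -0.05 there without treated replicate 2. Of 78 members, 0 were higher and 41 lower in WERI, or 60 lower without treated Y79 replicate 2. In Y79 20 were higher and 1 lower. The gap from the median nuclear gene argues only against a rise of mitochondrial mRNA as the sole change, since that would lower all nuclear mRNAs alike. It was fixed in advance by medians known under TMM, 1.55 and 1.92 for ribosomal proteins beside 1.86 and 1.65 for mitochondrial mRNAs. A mitochondrial rise together with uneven changes of nuclear mRNAs would leave the same gap and stays open. The values are consistent with a fall of most nuclear mRNA that TMM centring hides. RNA per cell was not measured, so whether and how far most nuclear mRNA fell, and whether long-lived mRNAs rose at all, stays open.

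The second pattern weighed was the set of genes lower after THZ1, against 2 forms of length bias. Across genes, the rank correlation of exonic length with the log2 fold change was -0.107 in WERI and -0.048 in Y79. Transcript length as the cause in both lines required values under -0.1 in both. The Y79 value lies above this bound, which argues against that cause in Y79. In WERI the bound was passed by less than the bootstrap SD of 0.0079, so the test does not decide there. The bootstrap drew genes as if they were independent and holds no spread between cultures. With genomic length held fixed, the exonic correlations were -0.02 in WERI and 0.016 in Y79. With exonic length held fixed, the genomic ones were -0.101 and -0.086. For genomic length alone the rank correlation was -0.15 in WERI and -0.097 in Y79 with a bootstrap SD of 0.0081. Genomic length and the log2 fold change thus had a weak negative rank correlation in both lines. The value in Y79 lies within its spread of the same bound, and whether length accounts for the falls stays open. The trend was not steady. Medians in WERI and Y79 were 0.39 and 0.41 in the shortest 1 of 10 classes of genomic length, and -0.22 and -0.26 in class 7. In the longest class they were -0.16 and -0.03, so the longest genes fell less than those of class 7. Dependence of polymerase II on CDK7 and CDK12 is a biological explanation that stays open.

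The third pattern weighed was the low counts of WERI genes in treated Y79 libraries, which the values of CHRNB4, ZNF518B, H2AFY2 and DSC2 include. Of 54 genes with counts in WERI and next to none in Y79 controls, treated replicate 3 had counts for 44 (81.5%), at 0.538% of the WERI level and with a rank correlation to it of 0.51, so a small amount of WERI RNA or reads in that library is a candidate explanation. Treated replicates 1 and 2 had counts for 6 and 16 of them, and the controls for 8, 3 and 5, which argues against THZ1 switching these genes on as a set. TSTD1 does not follow the share, with 22, 43 and 20 counts where 0.303, 0.626 and 3.61 would be brought in, and DSC2 (6 and 3 counts in replicates 2 and 3, 1.53 and 5.78 expected) and ZNF518B (6 and 6, 3.29 and 12.4 expected) follow it only loosely, as does LYNX1 (2, 4 and 7, 0.768, 1.55 and 5.70 expected), so these values stay open. In the other direction, treated WERI libraries had counts for 5, 6 and 7 of 12 Y79 genes against 0, 0 and 3 in controls. Summed over these genes the treated counts made 1.99%, 4.15% and 0.374% of the Y79 level, without a positive rank correlation with it. This was not weighed further. The negative differences of H2AFJ, NEUROG1 and RNF26 rest on similarly low WERI counts and carry the same limit.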

How the results depend on the processing

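Leaving the unannotated loci out, the list counts under another scaling or without a replicate, and the bounded medians under another scaling, were chosen after the data were seen, and the other alternatives were planned. Numbers of genes are given as higher and lower, and within 1.5 times of the reported ones where not listed here. With DESeq2, RLE factors, no filter, the stricter filter, the samples of a comparison alone and the loci left out, all of these numbers stayed within that range.

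With library size only, higher genes numbered 2221 in WERI, 2175 in Y79 and 740 for the difference between the lines. Scaled to mitochondrial mRNAs they were 111 and 13328 in WERI, 283 and 12188 in Y79, 713 lower for the difference and 2706 higher for the lines in DMSO. This follows from the construction, since each scaling moves all genes of a library alike. The same scaling reversed MYC (-0.82), CDK12 (-1.85, from an uncalled value), GNGT1 (-0.44), PDE6A (-0.47), COX6C (-0.014), UQCRQ (-0.18), PGK1 (-0.28) and PDK1 (-0.45) in WERI, PDK1 (-0.076) in Y79 and the glycolysis list in WERI (adjusted p = 0.814). Of these genes only MYC, CDK12, PGK1 and PDK1 in WERI passed the threshold in the reversed direction, MYC with an adjusted p of 0.00299. CDK12 in WERI was also reversed with library size only (-0.41, adjusted p = 0.0282).

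The replicate block, which uses numbers that do not pair the samples (same-number correlations of -0.22 to -0.003 in WERI), gave 864 higher genes for the difference. Requiring a log2 fold change of at least 1 gave 1680 and 2476 in WERI, 2144 and 2953 in Y79, 284 and 358 for the difference and 1572 and 2721 in DMSO, fewer by construction.

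Leaving out 1 library at a time gave 3651 to 3781 higher and 5134 to 5366 lower genes in WERI, 4047 to 4388 and 5450 to 6001 in Y79, and 4265 to 4412 and 4457 to 4509 in DMSO. For the difference the ranges were 889 to 2161 and 1437 to 3029, with the lowest numbers without WERI_DMSO replicate 3 and the highest without Y79_THZ1 replicate 2. That replicate deviated most from its group (SD of log2 deviations 0.298, against 0.219 and 0.241 for the others).

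Of the values for named genes, 111 kept direction and side of the threshold with DESeq2, 112 with RLE factors, 107 with library size only and 90 under mitochondrial scaling. For lists, 107 did so with RLE factors, 102 with library size only, 86 under mitochondrial scaling and 79 with an estimated correlation, where 29 lost their call. Values that passed the threshold in neither setting count as kept whatever their sign. With fry, which asks another question and so can differ, 57 lists kept their side and 45 gained a call. It called 5 lists in the opposite direction to an uncalled camera test, namely retinal progenitor (0.0138), anti-apoptotic (0.0105) and p53 target genes (4.21e-05) in Y79 and glial (3.99e-06) and stromal genes (0.0039) in DMSO. Calls lost under mitochondrial scaling included photoreceptor genes in WERI (0.361), the nuclear respiratory chain in WERI (0.064) and Y79 (0.194) and glycolysis in Y79 (0.588). Some lists not called in the report passed under mitochondrial scaling. In WERI they included glial (0.00812), stromal (0.00061) and interferon genes (0.014), toward higher than other genes, and repair genes (0.0201), toward lower. Of the glial and stromal lists, 14 of 21 and 10 of 19 members were tested. The scaling moves all genes of a library alike, so calls gained or lost under it are not read as responses of the lists. The histone call in DMSO was lost with the stricter filter (0.104) and with the DMSO samples alone (0.17), and the interferon call there with library size only (0.0716). The cause was not tested.

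Depth limits the genes at the floor. A gene with 0 counts in a group can be given only a bound, and simulated 1.5-fold differences between the lines' responses were recovered for 22.4% of genes.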
